A study of Micropogonias undulatus with 21 samples.

How the data were processed

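The deposited files hold one table per library with a TPM value for each of 26745 gene names. That the values are TPM is stated by the column name, per the file headers, and each library sums to 1000000. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and polyA libraries were made with the Illumina TruSeq stranded mRNA kit. CASAVA and FastQC are named in the submitters' processing notes. The aligner, the reference and the counting tool are not given in the sources used here. In the spleen files 13 gene names had been turned into dates and were matched to the names at the same rows of the liver files. The LOC names are not paired with gene names in the files, and at most a few are printed. Whether reads were counted by strand, and how reads shared by paralogs were assigned, is not given in the sources used here.

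TPM keeps no depth, but low values were whole multiples of the value of 1 read. Whole reads, within 0.003 of a whole number, were recovered for 18835 of 19072 genes positive in 5 or more libraries (98.8%); on simulated data every recovered count was exact. They give a part of the depth, 1492488 to 13892186 reads per library, over genes holding 32.8% to 73.9% of the TPM. They also served for an added limma-voom alternative, which therefore left out the genes holding the rest. A low depth or few molecules limits what small values can show, and liver library 2 of both exposures is the shallowest.

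Groups were taken from the sample titles: control, pathogen, oil, and oil and pathogen, in spleen and liver. The labels do not say that libraries of a group came from separate fish, so p-values measure the spread between these samples, which may be technical. The count test designed before the data were examined was replaced, as that design foresaw, by limma-trend with robust empirical Bayes (limma 3.58.1, R 4.3.3) on log2(TPM + 1), because the values are TPM. Genes with a TPM of 1 or more in at least 2 spleen libraries, 3 liver libraries, or 2 libraries for the comparison of tissues were kept (15913, 12236 and 16586 genes). A fold change on the log2(TPM + 1) scale understates the change of low genes. The 4 groups of a tissue shared one fit, with no replicate block, and the Benjamini-Hochberg threshold was 0.05. There were 6 comparisons per tissue and 3 tissue differences.

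A total of 35 gene lists was fixed before the data were examined. Members were matched by symbol, allowing a paralog suffix, which also took in cpd, hpdl, acadsb, cdc20b, rrm2b, ier5l and tapbpl, genes other than those listed. Lists with 5 or more measured genes were tested with camera (preset correlation and, as an alternative, estimated) and fry. In the main fits no camera call held with an estimated correlation, against 111 calls with the preset one over the 15 comparisons, and fry made 10. A scaled fit of the tissue difference for oil, added afterwards, did give such a call for B-cell markers (camera adjusted p = 0.0077). The correlation estimated there was -0.047, so that call made no allowance for correlated genes. Several lists that the tests called are given with their counts, and camera compares a list with all other genes while fry does not.

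Genes named in the text were set by a rule fixed in advance: up to 6 rises and 6 falls (5 and 5 for comparisons without control) of largest fold past the threshold, with a mean log2 value of 2 or more, no overlap of the libraries of both groups, and a gene symbol; up to 3 genes per list by p-value; and 10 genes always named where measured, of which only ahrr matched by symbol among the genes tested (cyp1a, cyp1b1, hamp, il1b, cxcl8, saa, hp, tnf and hmox1 did not). Where none passed, genes among the 5 smallest p-values were named as such. The text prints a selection of the genes the rule names, and 1 result is not reported here. The same rule was applied to the fits without liver control 2, which were added afterwards.

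Alternatives planned in advance were quantile normalization, no robust empirical Bayes, no filter, a pseudocount of 0.1, only the groups compared, the replicate number as a block, and leaving out each library. Alternatives added after the values were seen were median-ratio scaling, TPM rescaled without the 58 transcripts (100 TPM or more in spleen control 1 and at least 32 times control 2), limma-voom on recovered reads, and each of these without liver control 2 or, for scaling, without spleen control 1.

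The fit was tested on simulated data with 200 changed genes per comparison. Noise was drawn independently for each gene, with the same spread in every library and no outlying library. The rates below therefore do not measure recovery or false calls among correlated genes or uneven libraries such as those here. For oil minus control it recovered 7.46% of changes of log2 2 and 22.4% of log2 3 in spleen, and 47.8% and 76.1% in liver; 4 and 5 unchanged genes were called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.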

Results

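RNA of spleen and liver from juvenile Atlantic croaker (Micropogonias undulatus) was sequenced after exposure to oil, to a bacterial pathogen, to both, or to neither. The oil was a high-energy water-accommodated fraction of Macondo well oil, a dispersion of oil in water, given for 8 days at 541.181 µg/L. The pathogen was Vibrio anguillarum, a marine bacterium that infects fish, given for 1 h, 24 h before sampling. The 21 libraries comprised 9 from spleen (2 control, 2 pathogen, 2 oil, 3 oil and pathogen) and 12 from liver (3 per group). Values were transcript shares scaled to a sum of 1000000 per library (TPM) for 26745 genes, of which 15349 carried only a LOC identifier that the files do not pair with a name. Reads recovered from the steps of the TPM values ranged from 3763419 to 7991233 per spleen library and from 1492488 to 13892186 per liver library, over genes holding 32.8% to 73.9% of the TPM. In the control libraries, 14 of the 16 measured genes of the hepatocyte list were lower in spleen than in liver past the threshold, as the tissue labels require. Fold changes are differences of log2(TPM + 1) with the standard error (SE) of the limma fit, and adjusted p-values are Benjamini-Hochberg values of limma.

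Libraries within groups stood apart in several respects. A set of 58 transcripts, among them the pancreatic digestive enzymes cpb1 and amylase, held 68.4% of the TPM in spleen control 1 and 0.57% in spleen control 2. In liver the same 58 transcripts held 49.0% and 41.4% of the TPM in controls 1 and 3, 3.43% in control 2, 41.9% to 46.3% in the pathogen livers, 3.59% to 9.69% in the oil livers and 16.5% to 21.8% in the livers given both. The library labelled liver control 2 also listed 14731 genes at 0, against 9948 to 12396 in the other liver libraries. In spleen pathogen 2 the top gene held 20.6% of the TPM and the top 10 genes 46.2%, against 1.81% and 12.7% in spleen pathogen 1. The 58 transcripts held 4.07%, 19.1% and 14.6% in spleen libraries 1, 2 and 3 of both exposures. Because TPM adds up to a fixed sum, a library with a large share in few transcripts has lower values for all others. The median log2 fold change over all genes was 1.15 for oil minus control in spleen and 0.67 in liver. After scaling each library on its median ratio it was 0.02 and 0.03. That scaling brings the median near 0 by construction, so these values do not show what shifted it.

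**Figure D1:**
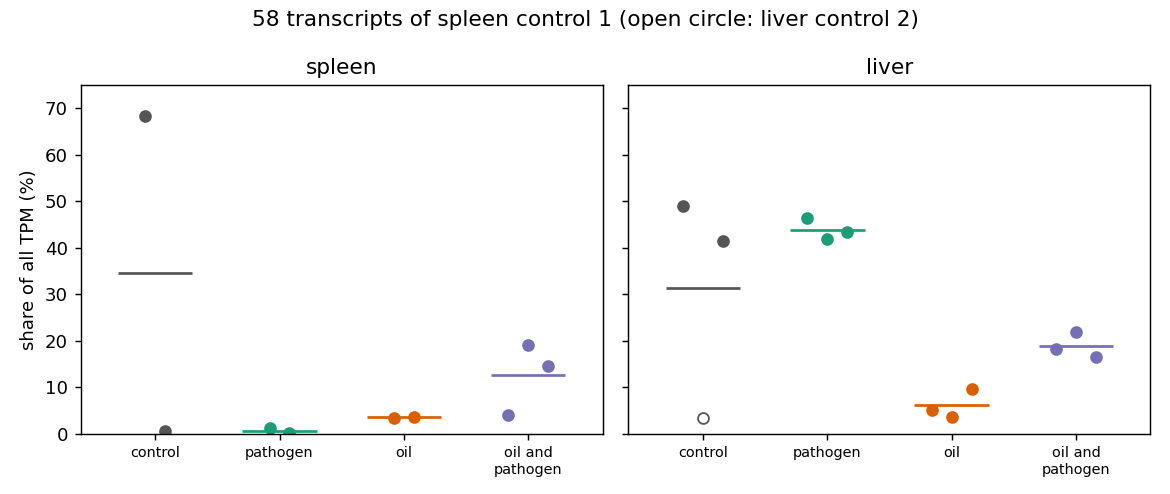
Share of all TPM (%, vertical axis) held by the 58 transcripts abundant in spleen control 1, per library (points) and group mean (lines), in spleen (left) and liver (right); the open circle is liver control 2. Spleen control 1 lies at 68.4%, and liver control 2, at 3.43%, lies below the other liver controls at 41.4% and 49.0%.

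Oil alone in the spleen raised ahrr, the aryl hydrocarbon receptor repressor and a target of that receptor, from 0.755 ± 0.819 TPM in controls to 74.5 ± 43.0 TPM (SD, n = 2 each), a log2 fold change of 5.38 (SE 0.92, limma adjusted p = 1.7e-05). The matrix metalloproteinase gene mmp9 rose by 4.99 (SE 0.90, limma adjusted p = 7.9e-05). Cell-cycle genes were higher, with ccnb1 (cyclin B1) up by 4.90 (SE 0.94) and ccna2 (cyclin A2) by 4.68 (SE 0.92). The B-cell receptor chain gene cd79a fell by 4.04 (SE 0.92, limma adjusted p = 0.0041), from 59.8 ± 15.3 to 3.11 ± 2.70 TPM. Further rises were rrad at 4.41 (SE 0.92) and the serine protease gene htra1 at 4.29 (SE 0.91). Some of these rises rested unequally on the oil libraries: ccnb1 stood at 1677 TPM in oil 1 and 23.7 TPM in oil 2, and mmp9 at 2346 and 70.8 TPM. Without oil 1 their log2 fold changes were 1.85 and 2.47, and that of ccna2 was 1.70; without spleen control 1 that of rrad was 2.79. Across 15 alternatives these calls held in 4 for ccnb1 and ccna2, 5 for mmp9 and rrad, and 6 for htra1 and cd79a.

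All 39 measured genes of the cell-cycle list were higher in the oil spleens, 13 past the threshold over all genes and 37 when adjusted over the list alone, with a median 1.52 above that of all genes (camera adjusted p = 3.4e-21; adjusted p = 0.91 with an estimated correlation). After median-ratio scaling none of the 39 passed, over all genes or adjusted over the list alone. All 25 proteasome genes were higher, 0 past the threshold over all genes and 24 adjusted over the list alone (camera adjusted p = 4.8e-06; adjusted p = 0.91 with an estimated correlation). The 63 cytosolic ribosomal protein genes lay 1.06 below the median of all genes (camera adjusted p = 3.3e-11; adjusted p = 0.91 with an estimated correlation); 52 were higher than in controls before scaling and 0 after it. Of 7 B-cell markers 1 fell and, relative to all genes, their median was -1.77 (camera adjusted p = 5.4e-06; adjusted p = 0.91 with an estimated correlation).

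Over all 15913 spleen genes, 245 rose and 9 fell with oil alone. Median-ratio scaling gave 4 up and 8 down, quantile normalization 2 up and 9 down, and limma-voom on the recovered reads 0. Without spleen control 1 the counts were 2 up and 0 down, without spleen control 2 they were 10037 and 81, without oil 1 they were 2 and 0, and without oil 2 they were 721 and 12. After scaling, ahrr remained up by 4.54 (SE 0.49, limma adjusted p = 0.03), while vgll3 fell by 3.91 (SE 0.37) and the B-cell coactivator gene pou2af1 fell by 3.26 (SE 0.42); ahrr missed the threshold without spleen control 1 (limma adjusted p = 0.072) and without oil 1 (limma adjusted p = 0.11), and passed it in 8 of 15 alternatives (log2 fold 4.42 to 6.76).

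**Figure D2:**
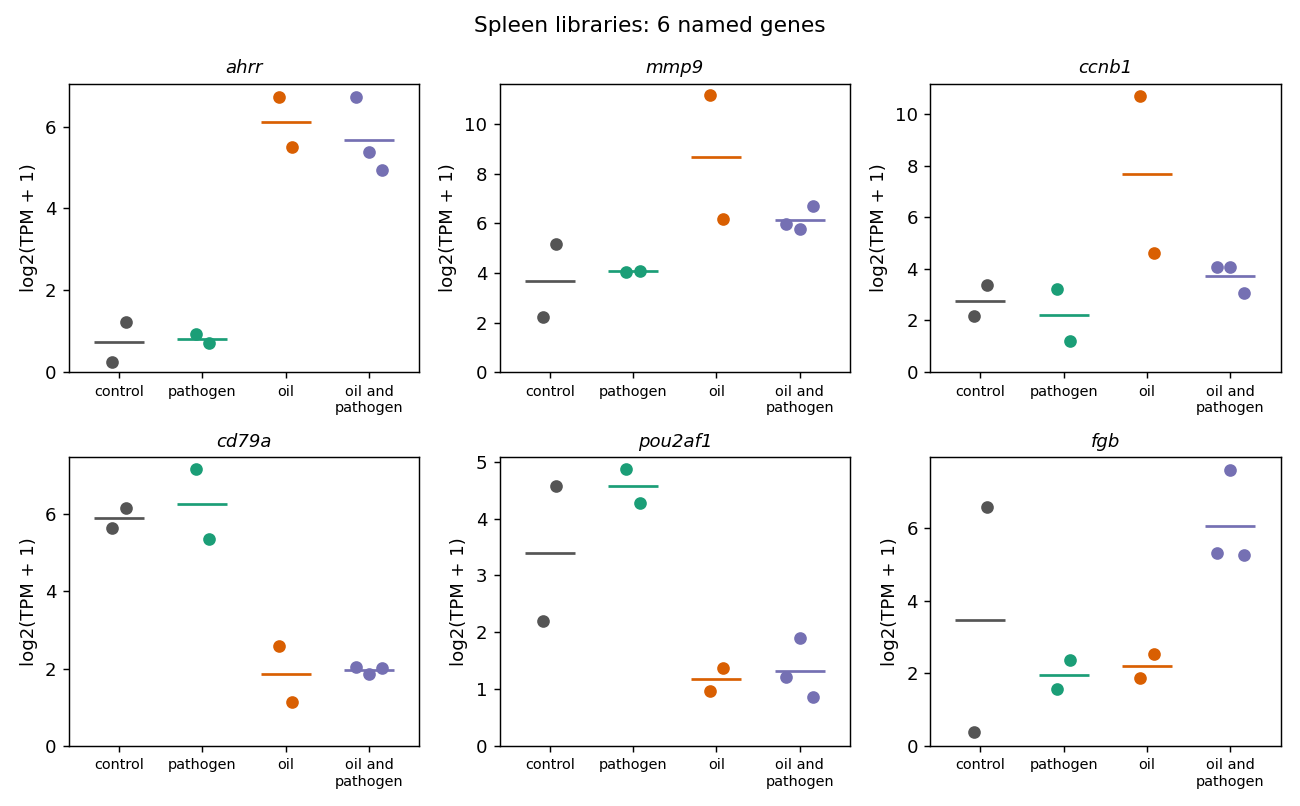
Level of 6 named genes, as log2(TPM + 1) on the vertical axis, in each spleen library (points) by group, with group means (lines). All 5 libraries given oil, alone or with the pathogen, lay between 29.4 and 104.9 TPM of ahrr and the 4 others between 0.18 and 1.33 TPM.

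Few genes were called for pathogen exposure alone in the spleen, where simulated changes of log2 2 were recovered in 2.99% and of log2 3 in 32.8%. No gene with a name passed the threshold; 3 LOC genes fell, among them LOC104930138 with a log2 fold change of -5.38 (limma adjusted p = 8.03e-06) and LOC104940098 with -4.30 (limma adjusted p = 0.0104), named after their values were seen. The gene ahrr stood at 0.768 ± 0.198 TPM against 0.755 ± 0.819 TPM in controls (log2 fold change 0.09, SE 0.92, n = 2 each, limma). Hepatocyte markers lay 1.21 below the median of all genes (camera adjusted p = 2.6e-09; adjusted p = 0.84 with an estimated correlation), and 7 of 7 erythroid markers were higher (camera adjusted p = 0.00011; adjusted p = 0.84 with an estimated correlation). Single libraries carried both shifts. The hepatocyte list averaged 0.37 and 9.23 TPM in controls 1 and 2 and 0.46 and 1.22 TPM in the pathogen spleens, and the erythroid gene alas2 stood at 95.9 and 775 TPM in the controls, 128 TPM in pathogen 1 and 4730 TPM in pathogen 2. With limma, 177 of 15913 genes had an unadjusted p under 0.05, below the share of 0.05 that unchanged genes would give on average. Each scaling alternative and limma-voom gave 0 genes, as did leaving out spleen control 1 or pathogen 2; without spleen control 2 the counts were 2034 up and 81 down, and without pathogen 1 they were 7 and 10.

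Exposure to both oil and pathogen raised ahrr in the spleen by 4.95 against control (SE 0.84, limma adjusted p = 1.1e-05), to 58.2 ± 40.3 TPM (SD, n = 3). The stress-response gene ddit4 rose by 3.18 (SE 0.81), the lysosomal protease gene ctsl by 3.17 (SE 0.76), htra1 by 3.25 (SE 0.83) and tpd52l1 by 3.11 (SE 0.79). The gene cd79a fell by 3.93 (SE 0.84, limma adjusted p = 0.0028). Apart from ahrr these calls held in few alternatives: 2 of 16 for ddit4, 3 of 15 for ctsl, 3 of 16 for htra1 and tpd52l1, and 4 of 16 for cd79a. Without spleen control 1 the fold of ddit4 was 1.34 and without control 2 it was 5.01. Macrophage markers were higher in 6 of 6 genes, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00029; adjusted p = 0.85 with an estimated correlation). In all, 37 genes rose and 2 fell; median-ratio scaling gave 2 up and 0 down, with ahrr at 4.39 (SE 0.45, limma adjusted p = 0.032). Without spleen control 1 there were 2 up and 0 down and ahrr missed the threshold (limma adjusted p = 0.12), and without spleen control 2 there were 9386 up and 35 down; leaving out a library given both exposures gave 8, 15 and 12 up for libraries 1, 2 and 3.

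Of the genes that rose with oil alone, 33 also rose with both exposures, and 2 fell in both; after median-ratio scaling, 2 rises and 0 falls were shared, of 4 and 2 rises. Without scaling, independent lists of these lengths would share 0.57 rises. Simulated unchanged groups set against a common simulated control group shared 4.01 genes on average, with a 95th percentile of 14.1. The covariance of the fold changes was 0.341, against 0.249 on average and 0.518 at the 95th percentile in the simulations. With median-ratio scaling the simulated groups shared 26.8 genes on average, with a 95th percentile of 0. The simulations dealt the deviations of all spleen libraries to the groups at random, so the wide gap between the 2 controls was not kept in place. They therefore cannot show whether the overlap exceeds what these controls would give. The 2 controls cannot be divided further, so part of the overlap may come from the shared controls.

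Adding oil to pathogen exposure, a comparison in the spleen that uses no control library for its means, raised ahrr by 4.86 (SE 0.84, limma adjusted p = 1.3e-05) and the antibacterial siderophore-binding protein gene lcn2 by 4.24 (SE 0.83, limma adjusted p = 0.00023), from 3.49 ± 1.74 (n = 2) to 86.3 ± 41.3 TPM (n = 3). The gluconeogenic gene pck1 rose by 4.21 (SE 0.80), erp27 by 4.11 (SE 0.84) and the fibrinogen gene fgb by 4.08 (SE 0.88). The B-cell genes cd79a and pou2af1 fell, by 4.30 (SE 0.84, limma adjusted p = 0.0002) and 3.26 (SE 0.79). After median-ratio scaling ahrr (4.30, SE 0.45), lcn2 (3.57, SE 0.43), the macrophage receptor gene mrc1 (3.32, SE 0.42) and cebpa (2.37, SE 0.30) rose, and pou2af1 (-3.84, SE 0.38) and tnfrsf13b (-2.78, SE 0.36) fell.

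Of 14 measured hepatocyte markers in that comparison, 5 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 1.4e-11; adjusted p = 0.36 with an estimated correlation), and after scaling 0 passed. Complement genes were higher in 11 of 11, 10 of them past the threshold adjusted over the list alone (camera adjusted p = 4.3e-09; adjusted p = 0.36 with an estimated correlation). B-cell markers fell in 2 of 7 over all genes and 3 adjusted over the list alone; after scaling the fry test of a common direction gave an adjusted p of 0.0067 for them and 0.0069 for the macrophage markers, which were higher in 6 of 6 genes. The totals were 141 up and 8 down, 9 and 5 after median-ratio scaling, 9 and 10 after quantile normalization, 195 and 7 when rescaled without the 58 transcripts, and 0 with limma-voom. A limma fit of these groups alone gave 1368 up and 39 down, and 0 once scaled. Without pathogen 1 there were 42 up and 25 down (cd79a adjusted p = 0.27, lcn2 adjusted p = 0.12, limma; the calls of pck1, fgb and pou2af1 held in 7, 6 and 7 of 16 alternatives), without pathogen 2 there were 15 and 2, and without library 2 of both exposures 40 and 2.

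Adding pathogen to oil exposure raised genes abundant in liver within the spleen libraries: f2 (prothrombin) by 4.12 (SE 0.87, limma adjusted p = 0.0092), fgb by 3.86 (SE 0.88), plg (plasminogen) by 3.82 (SE 0.77), ambp by 3.14 (SE 0.79) and tat by 3.06 (SE 0.76). The gene ccnb1 fell by 3.93 (SE 0.86) and the lipid-droplet gene cidec by 3.53 (SE 0.75). Of the 14 hepatocyte markers, 3 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 3.9e-19; adjusted p = 0.50 with an estimated correlation). Spleen control 2 also held 94.2 TPM of fgb against 0.30 TPM in control 1, so these genes varied between libraries of one group. Across 16 alternatives each, the calls of f2 and fgb held in 4, that of plg in 6, those of ambp and tat in 2, and those of ccnb1 and cidec in 3. Without oil 1 the log2 fold change of ccnb1 was -0.88, that of ambp 2.21, and cidec fell by 2.00, none past the threshold, and without oil 2 that of ccnb1 was -6.97. The totals were 19 up and 8 down and became 0 with every scaling tried and with limma-voom; they were 0 without oil 1, 25 and 284 without oil 2, 1 and 2 without library 1 of both exposures, and 0 and 3 without library 2.

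The interaction in the spleen, the departure of the joint response from the sum of the separate ones on the log2 scale, was largest for fgb (5.37, SE 1.30, limma adjusted p = 0.036), f2 (5.16, SE 1.29), plg (5.03, SE 1.14, limma adjusted p = 0.015) and tat (4.58, SE 1.12). Hepatocyte markers lay 2.76 above the median of all genes, with 3 of 14 past the threshold and 7 adjusted over the list alone (camera adjusted p = 8.8e-26; adjusted p = 0.28 with an estimated correlation). For ahrr the interaction was -0.52 (SE 1.24, limma). In all 27 genes passed upward and 2 downward, and 0 did under each scaling alternative and limma-voom. These folds rested in part on spleen control 2: without it fgb was 2.27, f2 2.31, plg 2.91 and tat 2.52, and without control 1 they were 8.47, 8.01, 7.15 and 6.64, in neither case past the threshold. Without control 2, 25 genes passed, 6 of them among the 29. Without control 1, oil 1 or library 2 of both exposures 1 gene passed upward, without pathogen 1 there were 9 and without pathogen 2 there were 2, and without oil 2 there were 31 up and 153 down.

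In the liver, oil alone raised the heme-synthesis gene alad by 2.85 (SE 0.53, limma adjusted p = 0.017), the mitochondrial co-chaperone gene dnajc15 by 2.90 (SE 0.52) and hmgcs1, an enzyme gene of cholesterol synthesis, by 2.71 (SE 0.59). Further rises were cviiih15orf48 at 3.41 (SE 0.83), pmm1 at 2.82 (SE 0.76) and mrpl13 at 2.76 (SE 0.41). The caveolin gene cav1 fell by 1.23 (SE 0.31, limma adjusted p = 0.04), from 8.67 ± 0.892 to 3.14 ± 0.569 TPM (SD, n = 3 each). Oxidative phosphorylation genes rose in 10 of 48 over all genes and 25 adjusted over the list alone (camera adjusted p = 0.0005; adjusted p = 0.95 with an estimated correlation). Cholesterol biosynthesis genes were higher in 21 of 21, 3 past the threshold and 10 adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.95 with an estimated correlation).

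With the 3 liver controls as labelled, 701 of 12236 genes rose and 8 fell with oil, and 0 passed after median-ratio scaling, after quantile normalization or with limma-voom. Without the library labelled liver control 2, 6563 genes rose and 167 fell, and after scaling 477 rose and 593 fell (limma-voom gave 300 and 535). Leaving out liver control 1 or oil 1 gave 0, control 3 gave 453 and 6, oil 2 gave 90 and 1, and oil 3 gave 161 and 2. The gene alad missed the threshold without control 1 (limma adjusted p = 0.062), and cav1 without control 1 (limma adjusted p = 0.10). Across 20 alternatives the calls held in 10 for alad, 11 for mrpl13, 8 for dnajc15, 7 for hmgcs1 and cav1, and 3 for pmm1 and cviiih15orf48, whose folds without oil 1 were 1.88 and 2.48.

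Without the library labelled liver control 2, a choice made after the values were seen, the named genes with the largest rises in the oil livers included endoplasmic reticulum chaperone genes. The chaperone gene hspa5 rose by 5.71 (SE 0.70, limma adjusted p = 0.00049), from 13.9 ± 1.87 TPM in controls 1 and 3 to 981 ± 784 TPM (n = 3), and after scaling by 4.45 (SE 0.69). The disulfide isomerase gene pdia4 rose by 5.20 (SE 0.52), creld2 by 5.01 (SE 0.50) and hyou1 by 4.60 (SE 0.50), and after scaling by 3.97, 4.05 and 3.43. The proteasome genes psma2 and psmc4 rose by 4.43 (SE 0.54) and 4.25 (SE 0.50), and by 3.26 and 3.11 after scaling. The pancreatic carboxypeptidase gene cpb1 fell by 3.78 (SE 0.51), amylase by 3.00 (SE 0.47), pglyrp2 by 3.05 (SE 0.45) and dmgdh by 4.14 (SE 1.39). The gene ahrr rose by 1.69 (SE 0.38, limma adjusted p = 0.004) and by 1.22 (SE 0.32, limma adjusted p = 0.04) after scaling.

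In the same fit all 25 proteasome genes rose, 23 of them after scaling (camera adjusted p = 8.9e-21 scaled; adjusted p = 0.35 with an estimated correlation), and 22 of 24 genes of endoplasmic reticulum stress rose, 13 after scaling (camera adjusted p = 4.1e-09 scaled; adjusted p = 0.35 with an estimated correlation). The fry test gave an adjusted p of 0.0058 for either list after scaling. Cytosolic ribosomal protein genes changed with the scaling: 1 of 63 rose before it, and 41 fell after it, 62 adjusted over the list alone (camera adjusted p = 2.2e-27; adjusted p = 0.35 with an estimated correlation). After scaling, 4 of 8 mucosal, endothelial and stromal markers fell, with the collagen gene col1a2 at -3.14 (SE 0.38) and dcn at -1.84 (SE 0.39). Camera gave this list an adjusted p of 0.0052, and of 0.35 with an estimated correlation.

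**Figure D3:**
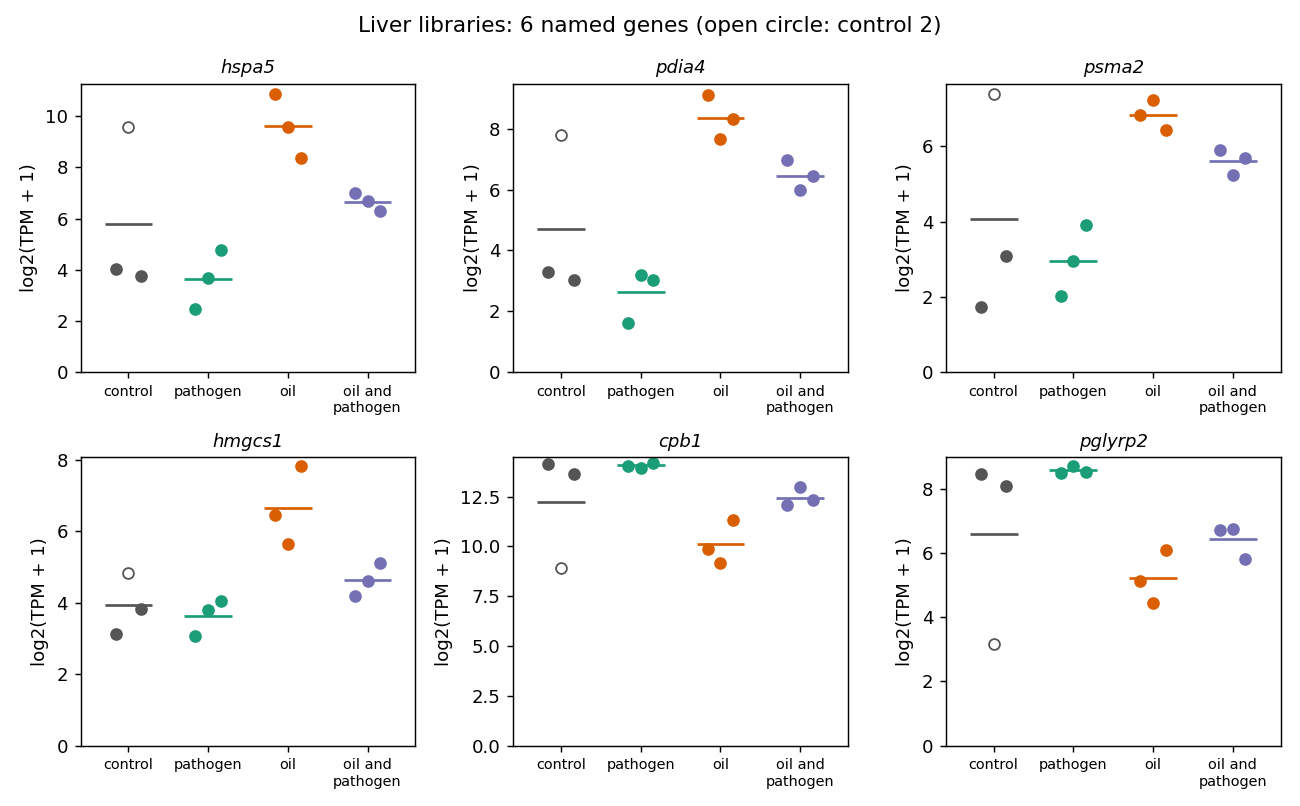
Level of 6 named genes, as log2(TPM + 1) on the vertical axis, in each liver library (points) by group, with group means over all libraries (lines); the open circle is the library labelled control 2. For hspa5 the oil livers averaged 981 TPM, controls 1 and 3 averaged 13.9 TPM, and the open circle lies among the oil livers.

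Pathogen exposure alone gave no liver gene past the threshold with limma. It gave 0 genes also with quantile normalization, median-ratio scaling and limma-voom, with or without liver control 2. With limma, 207 of 12236 genes had an unadjusted p under 0.05, below the share of 0.05 that unchanged genes would give on average. The smallest p-values belonged to rem1 (0.95, SE 0.25), rnpc3 (-1.28, SE 0.39), ptf1a (1.41, SE 0.46), ins (-3.14, SE 1.05) and ppcdc (-1.24, SE 0.42), each with a limma adjusted p of 0.82. Proteasome genes were lower in 25 of 25 (camera adjusted p = 0.0003; adjusted p = 0.92 with an estimated correlation), but in 6 of 25 without liver control 2. In simulated data for this comparison, 31.3% of changes of log2 2 and 85.1% of log2 3 were recovered, so smaller changes would mostly go undetected.

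Both exposures against control gave 0 liver genes with limma, with 1327 at an unadjusted p under 0.05, and 0 with limma-voom. Without liver control 2 there were 1258 up and 37 down, and after scaling 12 up and 21 down. In that scaled fit usp14 rose by 2.46 (SE 0.39), alad by 2.32 (SE 0.33) and txndc12 by 1.95 (SE 0.28), while col1a2 fell by 2.98 (SE 0.38), the lipid-transfer gene pltp by 2.24 (SE 0.35) and rtn1 by 2.20 (SE 0.29). Oxidative phosphorylation genes were higher in 47 of 48 with all libraries (camera adjusted p = 3.2e-09; adjusted p = 0.96 with an estimated correlation).

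Adding oil to pathogen exposure in liver involves no control library, yet gave 0 genes with limma (1706 at an unadjusted p under 0.05) and 0 with limma-voom in the fits whose 4 groups share one estimate of the spread. A limma fit of these groups alone, planned before the data were examined, gave 1100 up and 50 down of 10683 genes, and 17 up and 39 down after scaling. In it pdia4 rose by 3.84 (SE 0.46, limma adjusted p = 0.014), hspa5 by 3.03 (SE 0.53) and the retinol carrier gene rbp4 by 2.84 (SE 0.34), while pglyrp2 fell by 2.15 (SE 0.32), cpb1 by 1.61 (SE 0.26) and col1a2 by 1.54 (SE 0.34). Scaled values were 3.24 for pdia4, -2.81 for pglyrp2 and -2.27 for cpb1. Proteasome genes rose in 24 of 25 (camera adjusted p = 2.9e-13; adjusted p = 0.71 with an estimated correlation), and endoplasmic reticulum stress genes in 16 of 24 (camera adjusted p = 7.5e-08; adjusted p = 0.71 with an estimated correlation). After scaling these lists had 0 and 1 genes past the threshold over all genes, and 23 and 11 adjusted over the list alone. In the fit of all groups without liver control 2, scaled, 45 genes passed.

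Adding pathogen to oil exposure gave 0 liver genes with limma, with 864 at an unadjusted p under 0.05, and 0 under each scaling, with limma-voom and without any single library of these 2 groups. Cholesterol biosynthesis genes were lower in 21 of 21, 4 past the threshold adjusted over the list alone (camera adjusted p = 3.5e-05; adjusted p = 0.99 with an estimated correlation). The interaction in liver also gave 0 genes with limma and 0 with limma-voom. In it 366 of 12236 genes had an unadjusted p under 0.05 with limma, below the share of 0.05 that unchanged genes would give. Cholesterol biosynthesis genes were lower in the interaction in 20 of 21 (camera adjusted p = 0.00012, and 0.99 with an estimated correlation).

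The responses of spleen and liver were compared directly as spleen minus liver differences. For oil, 4 LOC genes responded more in spleen, among them LOC104928862 (6.21, limma adjusted p = 0.00125) and LOC104927071 (5.07, limma adjusted p = 0.00953). For both exposures 1 LOC gene did. These were named after their values were seen. The difference for ahrr was 4.31 (SE 0.89, limma adjusted p = 0.06) for oil and 4.11 (SE 0.85, limma adjusted p = 0.11) for both exposures. Its larger rise in spleen on the log2(TPM + 1) scale thus missed the threshold without scaling. That scale understates the change of low genes, and ahrr was low in liver. It stood at 0.04 and 0 TPM in liver controls 1 and 3, 2.64 TPM in control 2 and 1.12 to 4.27 TPM in the oil livers. The values therefore do not show that ahrr rose by a larger ratio in spleen. After median-ratio scaling, 1 of the 4 measured genes of the aryl hydrocarbon receptor list passed upward for oil. For oil the difference was above 0 in 38 of 39 cell-cycle genes, 0 past the threshold over all genes and 30 adjusted over the list alone (camera adjusted p = 7.1e-24; adjusted p = 0.43 with an estimated correlation). Both after median-ratio scaling and without spleen oil 1, fits of this list added after its values were seen, it was again above 0 in 38 of 39, and 0 passed adjusted over the list alone; the median difference, 2.37 before, was 1.28 in each. In the scaled fit the difference was below 0 in 6 of 7 B-cell markers, 3 past the threshold over all genes. Camera with an estimated correlation gave these an adjusted p of 0.0077, and fry gave 7.3e-06. The estimated correlation was -0.047, so the camera value made no allowance for correlated genes. For the same list it was 0.49 in the unscaled fit without spleen oil 1. The difference was below 0 in 10 of 10 T and NK cell markers (fry adjusted p = 0.017) and above 0 in 6 of 6 macrophage markers (fry adjusted p = 0.028). Lymphocyte markers were low in liver, where cd79a was at most 0.67 TPM. In the liver fit of the pathogen and joint exposure groups alone, 0 T and NK and 2 B-cell markers passed the filter. For genes so low in liver the difference mostly repeats the spleen change. Without spleen oil 1, in a fit without scaling, the difference was below 0 in 4 of 7 B-cell and 5 of 10 T and NK cell markers. Relative to all genes their medians were -1.36 and -0.27 in that fit. It changed both the scaling and the libraries, so it does not show what oil 1 contributed. For pathogen alone 0 genes differed with limma, and 0 after either scaling. Of 16586 genes, 271 had an unadjusted p under 0.05 with limma, below the share of 0.05 that unchanged genes would give on average. Median-ratio scaling gave 35 genes for oil, 13 up and 22 down. Without spleen control 2 the counts were 118, 2880 and 4954 for pathogen, oil and both, and without spleen oil 2 there were 755 for oil. The count for pathogen was 9 without spleen pathogen 1. That for oil was 36 without spleen control 1, 8 without spleen oil 1, and 2 without liver control 1, oil 1 or oil 3. That for both was 8 without spleen control 1, 11 and 0 without spleen libraries 3 and 1 of both exposures, 4 without liver control 3, and 0 without liver control 1 or 2 or any liver library of both exposures.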

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

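Every test of an explanation in this part, its bounds included, was written down only after related values had been seen, so each outcome is a hypothesis. In the spleen 29 genes responded to both exposures together otherwise than the separate responses add up to. The response to oil differed between spleen and liver in 4 genes, and the response to both exposures in 1. Leaving out 1 library gave 1 to 184, 2 to 2880 and 0 to 4954 genes. These were picked out because a test of the difference itself passed its threshold.

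Genes of the hepatocyte list were among the largest of the spleen interaction, in part through spleen control 2, whose list mean was 9.23 TPM against 0.37 in control 1; without it fgb was 2.27 in place of 5.37, and 6 of the 29 genes passed. Liver RNA carried into spleen libraries is a candidate explanation. Among 101 transcripts with at least 500 TPM in liver and under a thousandth of that in spleen pathogen 1, the median spleen level was 0.315%, 1.47% and 0.362% of the liver level in the 3 libraries of both exposures, 0.0124% and 0.0571% in the oil libraries and 0.664% in control 2. If liver RNA were the source, the ratios would lie close together: at least 80% within 2-fold of their median was required, and 51.5% was the lowest of the 3 libraries, which decides nothing since the bound for exclusion was 50%. A first run with a window of 4-fold and a higher minimum level had met the requirement. Over these 101 transcripts the lowest share within 4-fold was 84.2%, so the outcome turns on the window. The shares within 2-fold were 66.3% and 68.3% in libraries 1 and 2 of both exposures. They were 75.2% in the unexposed control 2, and 18.8% and 42.6% in the oil libraries. A response of the spleen to the joint exposure stays open, but would not account for the level in control 2.

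Among the liver splits, the spleen having too few libraries, other divisions of the same 6 libraries were too few for a share under 0.05. For oil minus control the real count was 709, reached by 2 of 10 splits, and the highest other was 3332, which put control 2 with oil 1 and oil 2 and so points to a structure of the samples. For pathogen minus control, both minus control, both minus oil and both minus pathogen the real count was 0, which all 10 splits reach by construction, and the highest others were 0, 4, 1 and 0. For the interaction all 100 drawn splits likewise reach the real 0, so they test nothing; the highest other, 4431, again put control 2 with oil 1 and oil 2, as did 6 of the 7 splits above 0, and so points to a structure of the samples.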

How the results depend on the processing

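Chosen after the values were seen were median-ratio scaling, rescaling without the 58 transcripts, limma-voom, and the combinations with scaling or with a library left out; the others were planned. Counts of genes past the threshold are given as up and down in brackets where directions matter. The liver comparisons pathogen minus control, both minus oil and the interaction stayed at 0 in every alternative run. Where a count changed, the cause was not tested, except that fewer libraries or more genes tested follow from the alternative itself.

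With quantile normalization the spleen counts were 0 for pathogen minus control, 11 (2 and 9, a reversed split) for oil minus control, 2 for both minus control, 0 for both minus oil, 19 (9 and 10, reversed) for both minus pathogen and 0 for the interaction; oil minus control in liver gave 0, and the tissue differences 21 for oil and 8 for both. With median-ratio scaling these were 0, 12 (4 and 8, reversed), 2, 0, 14 and 0 in spleen, 0 in liver, and 35 and 11. Rescaled without the 58 transcripts, they were 0, 33, 9, 0 and 0 in spleen for pathogen, oil and both minus control, both minus oil and the interaction, 202 (195 and 7, with 51 of the 149 shared) for both minus pathogen, and 0 for oil in liver. With limma-voom all 6 spleen counts and oil in liver were 0; at an unadjusted p under 0.05 it gave 1378 genes for oil and 1829 for both minus pathogen in spleen. With scaling and without spleen control 1 the spleen counts were 0, except 20 for both minus pathogen.

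Without robust empirical Bayes, pathogen minus control in spleen gave 50, both minus oil 107 (36 and 71, reversed), the interaction 109 and the tissue difference for both 0. With no filter, the spleen counts were 0 for pathogen minus control, 2 for oil, 0 for both, 0 for both minus oil, 7 for both minus pathogen and 0 for the interaction, and the tissue differences were 16, 20 and 0. With a pseudocount of 0.1 they were 16 for pathogen, 62 for both, 26 (8 and 18, reversed) for both minus oil and 17 for the interaction in spleen, and 257 for oil in liver. With only the groups compared, spleen gave 0 for pathogen, 0 for oil, 11 for both, 1 for both minus oil and 1407 for both minus pathogen, and liver 0 for oil and 1150 for both minus pathogen; with scaling as well, 0, 2, 0, 0 and 0 in spleen, and 0 and 56 in liver.

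Without liver control 2 and with median-ratio scaling, liver gave 1070 for oil (477 and 593, reversed), 33 for both minus control and 45 for both minus pathogen, and the tissue differences 36 and 7. Rescaled without the 58 transcripts, these liver counts were 1905, 52 and 48; with limma-voom 835 (300 and 535, reversed), 5 and 5; with quantile normalization 975 (477 and 498, reversed), 36 and 42.

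With the replicate number as a block, the spleen counts were 1 for pathogen, 92 for oil and 13 for both against control, and the tissue difference for both was 2. Between groups of a tissue, the numbers showed no steady pairing. Correlations of same-number deviations ran from -0.287 to 0.333 over 12 pairs in spleen and from -0.245 to 0.528 over 18 pairs in liver. In either tissue 3 of them were above 0.1. In spleen groups of 2 libraries the deviations mirror each other, so values such as 0.333 occur more than once. The 12 spleen values are therefore not independent and say little about pairing. Spleen was not paired with liver.

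Leaving out 1 library of the groups compared at a time, where a group left with 1 library is assumed to vary like the others, gave 0 to 2115 genes for pathogen minus control in spleen, 2 to 10118 for oil, 2 to 9421 for both, 0 to 309 for both minus oil (reversed at 309), 17 to 119 for both minus pathogen and 1 to 184 for the interaction (reversed at 184). In liver the ranges were 0 to 6730 for oil and 0 to 1295 for both, each highest without control 2, and 0 to 0 otherwise. The tissue differences ranged from 0 to 118, 2 to 2880 and 0 to 4954. In spleen the highest counts against control came without control 2 and the lowest, some of them tied, without control 1.

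Gene lists called in the main fits of the 15 comparisons numbered 0 with an estimated correlation and 10 with fry, against 111. The genes shared by oil and by both in spleen numbered 17 at an adjusted p of 0.01 and 54 at 0.1, against 35. Of 1445 alternative values for 81 results of named genes, 985 kept direction and side of the threshold, and 432 kept direction and lost the call. A further 28 gained it and 0 changed direction. The 985 include results never past the threshold, so they do not measure how often calls held. Among the calls themselves, more alternative values lost the call than kept it. For pairwise calls, the rule of no overlap between libraries keeps the direction whenever a library is left out. The recovered reads, 1492488 in the shallowest liver library, limit genes of low level, and in simulated spleen data changes of log2 2 were recovered in 0% to 11.9% and of log2 3 in 4.48% to 53.7%.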

Other observations

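The median-ratio scaling and all tests of explanations in this part, with their bounds, were chosen after the results were seen. Other gene lists in the spleen were tested for oil: after median-ratio scaling 9 of 9 T and NK cell markers were lower in the oil spleens, 0 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 5.4e-07; adjusted p = 0.43 with an estimated correlation). Macrophage markers were higher in 6 of 6 (fry adjusted p = 0.028). Without scaling the T and NK markers were lower in 5 of 9.

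The library labelled liver control 2 lay with the oil livers: on an axis over 1166 genes from control livers 1 and 3 (0) to oil livers 1 and 3 (1), it lay at 0.949, oil 2 at 0.977 and the pathogen livers between -0.03 and 0.11. Few molecules alone are argued against, since controls 1 and 3 drawn down to as many molecules stayed at -0.07 and 0.05. A candidate explanation is that it holds the same RNA as oil 2 in a library of few molecules: the spread of its read ratio to oil 2, over genes of 300 or more reads, was 1.51 times what about 11.3 reads per molecule predict, against 4.46 or more for every other liver library. Its ahrr level was 2.64 TPM, against 0.04 and 0 TPM in controls 1 and 3, at most 0.07 TPM in the pathogen livers and 1.12 to 4.27 TPM in the oil livers. A control fish unlike the others stays open, because 1.51 is above sampling noise although below the 3.67 that was the smallest among ordered pairs of the other liver libraries; the labels were kept as deposited.

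The 58 transcripts that fill spleen control 1 were lower in the oil livers, by a median of -3.02 on the log2 scale against controls 1 and 3, with 58 of 58 lower, and by -1.26 in the livers given both. The scaling of TPM is argued against as the whole cause, as 57 fell past the threshold with oil after median-ratio scaling without liver control 2, against 2 with both exposures. A smaller share of the tissue that makes them would lower all by one factor; their folds had an SD 1.78 times what the scatter between replicates predicts, between the bounds of 1.5 and 2, and 2.64 times the SD of their pathogen folds, so this cannot be told apart from a change within that tissue. Fewer acinar cells stay open as well: against control and pathogen livers, the summed TPM of 2 acinar transcription factor genes, ptf1a and bhlha15, had a log2 ratio of -0.11 and the 58 transcripts a median of -2.75 (SD 0.91), a gap of 2.65, and after median-ratio scaling -1.32 (bhlha15 alone -1.69) and -3.96 (SD 0.90), a gap of 2.64, which fewer cells alone would not give if each cell kept its level of both genes; that level was not measured, ptf1a had 2 reads in control 1 where 10 were required, and the rule of this test was rewritten 4 times with its values known, 2 of the 5 versions excluding the explanation and 3, the present one included, deciding nothing. A response to oil stays open and was not tested further.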
